A study of Mus musculus with 2 samples.

How the data were processed

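Total liver RNA was pooled per group, labelled and hybridised per the labels, with WT in Cy3 and CREBH KO in Cy5 on both arrays, 1 array for mice fed ad lib and 1 for mice fasted for 24 h. Both arrays lay on 1 slide and were read in 1 scan, so slide and scan could not differ between them. Sample titles name WT before KO, whereas the dye labels make every ratio of Cy5 over Cy3 a ratio of KO over WT, and this direction was used throughout. The lower Creb3l3 signal in the Cy5 channel goes with it on the fasted array under every normalization tried, and on the fed array except with centring on the median of all spots (log2 0.31).

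The authors deposited scanner output of Agilent Feature Extraction, version 10.10.1.1 per the file headers, and a value table. Spot and local background intensity per channel, as medians over pixels, were deposited as read by the scanner software, without normalization. The deposited processed intensity values had been background-subtracted, spatially detrended and dye-normalized with linear and lowess factors per the file headers. The deposited log10 ratio of each spot and its error are those of the scanner software, Cy5 over Cy3. The deposited p-value of each log ratio rests on that software's error model for 1 spot and not on replicates. The authors' value table holds log2 ratios that differed from the log10 ratios of the scanner files, turned to log2, by at most 0.005 when matched on the spot number, and both of its columns had a median of 0.00, so its scale and direction were settled from the data. Whether further centring was applied stays unknown. The array grid names mouse build mm9 per the file headers.

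Median spot signals were corrected for local background with normexp and an offset of 50, fitted on all spots, and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Mean spot signals had been planned and the medians were used in their place, since the scanner files used here carry medians. Channels were made comparable between arrays with Aquantile. Control spots (3671 per array) and spots the scanner software marked as outliers (216 fed, 197 fasted) were left out, and no gene spot was saturated. Spots of a probe were averaged. The offset draws ratios of dim genes towards 0. Median background-included signals were 27.0 (Cy3) and 83.0 (Cy5) on the fed array and 29.0 and 86.0 on the fasted array, over median backgrounds of 24.0, 69.0, 25.0 and 70.0. Observed against expected log ratios of the spike-in RNA, as given by the scanner software, had slopes of 0.956 and 0.960, so its ratios were compressed slightly. The slopes were not taken on the ratios normalized here, which the offset draws further towards 0.

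Probes carry accessions and no gene names. Unversioned RefSeq accessions were matched to the GRCm38.p6 gene table, which named 25934 of 26430 probes with NM accessions and 813 of 886 with NR accessions. Of 55681 probes 26762 were named, for 20284 genes, and 28919 were left unnamed. Since the builds differ, the table was used only for names and for which genes neighbour each other. For the 5405 genes with several probes the probe of highest mean intensity over both arrays was taken. Among genes 2-fold apart with another measured probe, that probe was under 0.5 on the log2 scale in the gene's direction for 1 of 12 genes (KO over WT, fed), 4 of 15 (fasted), 36 of 105 (fasting, WT), 53 of 122 (fasting, KO) and 4 of 24 (difference of ratios). Near-identical paralogs, such as Cyp4a10, Cyp4a31 and Cyp4a32, or Tgtp1 and Tgtp2, cannot be told apart with certainty by a probe.

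A gene was measured in a comparison when its probe was well above background, by the scanner software, in at least 50% of its spots in each channel compared. Genes above background on 1 side only have a bound, the bright normalized signal over the higher of the dim probe's own signal and the lowest signal of probes well above background in that channel. Comparisons were KO over WT per array, fasted over fed per genotype and the fasted minus the fed log2 ratio. With 1 pool per group no test was run, and a difference of at least 2-fold was the rule of size. The number of arrays limits the precision. Technical spread was taken from 399 probes printed 10 times. For 28 gene lists the median was placed among 10000 random lists matched on intensity in 20 bins, as a description of these pools. Over 5 comparisons 66 of 140 medians lay outside the 2.5 to 97.5 percentiles, and small medians there move with the normalization. If genes varied independently, 7.00 would lie there. Members of a list can vary together, lists overlap and the comparisons share channels, so 7.00 is not the number to be had by chance. Shares near Creb3l3 have exact Clopper-Pearson intervals.

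Genes named in the text were set by a rule fixed before the data were examined: Creb3l3, the 10 highest and 10 lowest named genes per comparison, up to 3 bounds per direction for KO over WT, and up to 4 members per list and comparison with the largest absolute log2 ratios. Cxcl14 in the fasted state and Gadd45g were added after their values were seen, as members of a small count. So were, in the closing part, the fed ratios of Arntl, Clock and Nfil3, and both KO over WT ratios of Sprr1a. The same holds there for the fasted over fed ratios of Nr1d1, Hlf, Dbp, Nr1d2 and Per2 in WT. It also holds for those of Usp2, Per1, Dbp, Tef, Nr1d2 and Per2 in KO. Some genes that the rule names are not reported here. The 2-fold rule was tested on simulated arrays of 55681 probes with known ratios: for KO over WT fed, 97.9% of 95 probes changed by a log2 ratio of 1.5 and 100.0% of 105 changed by 2 were recovered, with mean ratios of 1.34 and 1.82 and 0 false calls. For the fasted array 92.9% of 42 and 100.0% of 58 were recovered. Changed probes were drawn only from those bright over background in Cy3, so the recovery does not cover dim genes. Spot noise was simulated at a set size, so the 0 false calls hold for that noise only. Alternatives changed the background correction, the offset, the normalization within and between arrays, the signal columns, the filters, the handling of several probes, flagged spots and the neighbour window. Tables were computed with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in python 3.11.15, and plots drawn with matplotlib 3.10.9.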

Results

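Liver RNA of wild-type (WT) C57B6J mice was set against that of CREBH knockout (KO) mice in the fed state and after 24 h without food. CREBH, the product of Creb3l3, is a membrane-bound transcription factor of hepatocytes that is released and active in fasting. The data came from 2 two-colour expression arrays, 1 per feeding state, each with pooled WT liver RNA in the Cy3 channel and pooled KO liver RNA in the Cy5 channel, so 4 pools were measured once each. How many mice entered a pool is not given in the sources used here. There were no replicates and no dye swap, so a genotype difference within a feeding state, or its difference between states, had no test. A model of genotype and feeding state without their interaction would leave 1 residual degree of freedom and was not fitted, and all statements below describe these 4 pools by the size of the difference. Of 59305 gene spots, 39.9% (Cy3) and 42.9% (Cy5) were well above background on the fed array, and 45.9% and 45.8% on the fasted array. Technical spread came from probes printed 10 times: the median SD of the log2 KO over WT ratio between spots was 0.09 on the fed array (235 probes) and 0.08 on the fasted array (258 probes). It holds no difference between mice, pools or labelling reactions. A gene was counted as higher or lower when the ratio was at least 2-fold.

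Creb3l3 was lower in the KO pool in both feeding states. Its single probe (A_55_P2174987) had a log2 KO over WT ratio of -0.88 in the fed state, 1.84-fold lower, and of -2.07 in the fasted state, 4.21-fold lower. The scanner software gave errors of 0.22 and 0.28 on the log2 scale for these ratios. Fasted WT liver had more Creb3l3 signal than fed WT liver (log2 1.03), whereas the KO pools differed by -0.16. A signal well above background remained in the KO channel of both arrays, and whether the probe lies inside the deleted part of the gene is not given in the sources used here, so the residual signal says nothing about the allele. With each array centred on the median of all its spots in place of loess, the fed ratio turned to 0.31 and the fasted ratio was -1.11. That centring moved the median of all measured genes by 0.76 on the fed array and by 0.56 on the fasted array, less than it moved Creb3l3. Centred on the median of the measured genes, an alternative chosen after the data were seen, Creb3l3 was at -0.46 fed and -1.68 fasted.

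In fed liver, 13 of 34 measured genes of the interferon list were at least 2-fold lower in the KO pool than in the WT pool. So were Cyp4a14, Cyp4a31 and Cyp4a10. The interferon list holds genes of MHC class II. The lowest ratios were those of Tgtp2, an interferon-inducible GTPase (log2 -3.95, 15.5-fold lower), and Cyp4a14, a fatty acid hydroxylase under PPARα (-3.77, 13.6-fold lower). Cish, a suppressor of cytokine signalling, was at -2.67, the metallothionein Mt2 at -2.67, the GTPase Igtp at -2.46, the immediate-early gene Egr1 at -2.46 and Mfsd2a, a lysophospholipid transporter, at -2.33. Raet1e (-1.92), the GTPase Iigp1 (-1.80) and Phlda1 (-1.80) completed the 10 lowest. Highest in the KO pool was Moxd1, a monooxygenase-like gene (4.13, 17.6-fold higher), followed by Asns, which makes asparagine (2.19, 4.56-fold), the lipoprotein lipase inhibitor Angptl4 (1.84), the chemokine Cxcl14 (1.74) and the apolipoprotein gene Apoa4 (1.68). Txnip (1.64), Rgs16 (1.62), Lpin1 (1.59), Depp1 (1.41) and Zbtb16 (1.35) were also among the 10 highest. The other measured probe of Txnip was at 0.82, under 2-fold.

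Among the gene lists fixed before the data were examined, the interferon list had the median furthest from 0 in the fed comparison. All 34 of its measured members had ratios below 0, 13 of them at least 2-fold, and the median of -0.75 lay below that of all 10000 random lists of equal size and intensity. Over the alternatives that median ranged from -1.22 to -0.18. Cxcl9, a chemokine induced by interferon gamma, was at -1.71, and Cd74, the invariant chain of MHC class II, at -1.58. Kupffer cell and macrophage markers had a median of -0.21 over 20 genes, none of them 2-fold apart, with the scavenger receptor gene Marco at -0.91 and Cd5l at -0.57. Lymphocyte markers had a median of -0.17 over 11 genes and neutrophil markers of -0.21 over 6. Of 45 measured genes of fatty acid oxidation and ketogenesis, 4 were lower by at least 2-fold and none higher, namely Cyp4a14, Cyp4a31 (-1.61), Vnn1 (-1.57) and Cyp4a10 (-1.39). The 3 measured probes of Cyp4a31 ranged from -1.61 to -0.28 and those of Cyp4a10 from -1.72 to -0.88. The KO signal of Vnn1 (log2 6.18) lay near the lowest signal of probes well above background in that channel (6.08). In the clock list the median was 0.35 over 16 genes, with no gene 2-fold apart: Usp2 (0.92), Nr1d1 (0.78), Dbp (0.74) and Per1 (0.61) were the furthest from 0. Of 32 genes of the endoplasmic reticulum stress response, 28 had ratios above 0, with a median of 0.21, Derl3 at 0.86 and the chaperone gene Hspa5 at 0.67. Only Asns of that list passed 2-fold. CREBH targets known from other work had a median of -0.30 over 18 genes, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.08 and Apoa4 higher. With each array centred on the median of all its spots, the fed medians of CREBH targets (0.72), Kupffer cell and macrophage markers (0.57), lymphocyte markers (0.14) and neutrophil markers (0.49) turned to above 0.

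In total 63 of 11374 measured genes were at least 2-fold apart in the fed comparison, 18 higher and 45 lower in the KO pool. A further 2 genes were higher and 4 lower by at least 2-fold as a bound, being well above background in 1 channel only: Ctse was at least 2.21-fold higher, and the immediate-early gene Fos at least 2.19-fold and the ubiquitin-like gene Ubd at least 2.03-fold lower. These bounds are open to dye bias. Scanner-processed signals gave 173 genes, 62 higher and 111 lower. With each array centred on the median of all spots the split became 3103 higher against 9 lower.

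In fasted liver, 13 of 26 genes of cholesterol synthesis were at least 2-fold higher in the KO pool. Of 18 measured targets of CREBH, 7 were at least 2-fold lower. Apoa4 was 19.8-fold lower (log2 -4.31), Fabp2, a fatty acid binding protein gene, 16.1-fold lower (-4.01) and Mfsd2a 12.5-fold lower (-3.64). Tnfaip8l1 (-3.06), the glypican gene Gpc1 (-2.77), the fatty acid elongase gene Elovl2 (-2.57), the lipid droplet gene Cidec (-2.56), the fasting hormone gene Fgf21 (-2.36), Creb3l3 itself and Cgref1 (-2.04) completed the 10 lowest. Asns was 9.83-fold higher (3.30), and Sqle, which makes squalene epoxide, 5.63-fold higher (2.49). The oestrogen sulfotransferase gene Sult1e1 was at 2.42, Moxd1 at 2.19, the chemokine gene Cxcl1 at 1.92 and Lrtm1 at 1.79, and the remaining 4 of the 10 highest belonged to sterol synthesis: Idi1 (4.22-fold), Msmo1 (4.01-fold), Fdps (3.997-fold) and Hmgcs1 (3.65-fold).

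**Figure D1:**
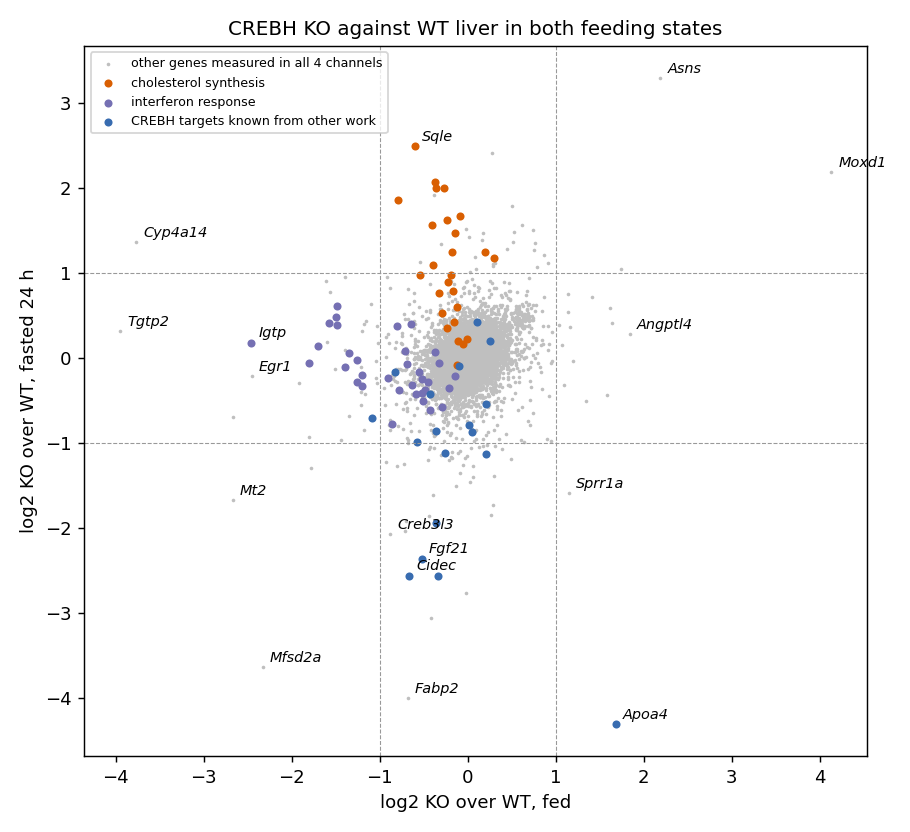
Each point is a gene measured in all 4 channels, with its log2 KO over WT ratio in the fed state on the x axis and after 24 h of fasting on the y axis; dashed lines mark 2-fold. Cholesterol synthesis genes lie high on the fasted axis with a median of 1.04, interferon genes lie low on the fed axis with a median of -0.75, and Apoa4 is at 1.68 fed and -4.31 fasted.

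Of 26 cholesterol synthesis genes, 13 were at least 2-fold higher in the fasted KO pool, none was lower by that much, and the median of 1.04 exceeded that of all 10000 matched random lists, with a range of 0.89 to 1.75 over the alternatives. Of 18 measured CREBH targets, 7 were at least 2-fold lower and none higher, with a median of -0.86, below all random lists, but of -0.01 with arrays centred on the median of all spots. The list was drawn from earlier work on this factor, and 17 of its 19 genes also stand in other lists. Among apolipoprotein and lipoprotein genes the median was -0.03 over 29 genes: Apoa4 and Apoa5 (-1.12) were lower, and Apoa1 was at -0.99. In the list of fatty acid synthesis and glycolysis the median was 0.18 over 31 genes, but the desaturase genes Fads2 (-1.94) and Scd1 (-1.92) and the elongase gene Elovl5 (-1.86), the 3 members past 2-fold, were all lower. Gluconeogenesis genes had a median of -0.27 over 19 genes, with Pck1 at -1.13 and G6pc at -0.87, though this median was 0.01 with arrays centred on the measured genes and 0.58 on all spots. Of 47 genes of fatty acid oxidation and ketogenesis, Pdk4 (1.56) and Cyp4a14 (1.36) were higher by 2-fold and Fgf21 lower, and the median was 0.08. The endoplasmic reticulum stress list again had 28 members above 0, of 33, with a median of 0.30 (Derl3 1.22), while Atf5 (-1.27) and Chac1 (-1.06) were lower. The lipid droplet list had a median of 0.00 over 31 genes, with G0s2, an inhibitor of lipolysis, at -1.73 and the fatty acid binding protein gene Fabp4 at 1.35. No interferon gene was 2-fold apart, and the median of that list was -0.13 over 36 genes, or 0.44 with arrays centred on the median of all spots.

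The fasted comparison held 97 genes at least 2-fold apart of 12263 measured, 44 higher and 53 lower. Gdpd3 was lower in the KO pool by a log2 bound of at least 1.72 and Slc13a5, a citrate transporter gene, by at least 1.32. Scanner-processed signals gave 193 genes and centring on the median of all spots 956, of which 940 were higher.

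**Figure D2:**
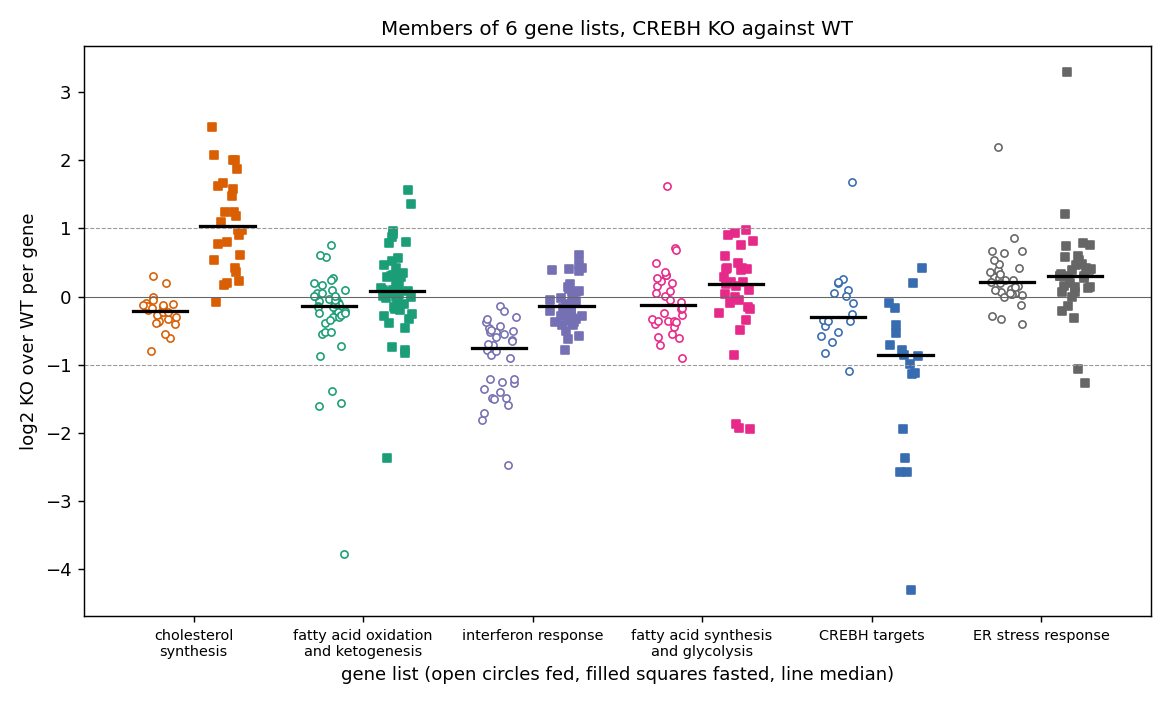
Log2 KO over WT ratios of the measured members of 6 gene lists, 1 point per gene, with open circles for the fed and filled squares for the fasted array and a black line at each median. The fasted cholesterol synthesis genes have a median of 1.04 against -0.21 when fed, and the fed interferon genes a median of -0.75 against -0.13 when fasted.

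In WT liver, fasting went with higher fatty acid oxidation genes and lower lipogenic and cholesterol synthesis genes. The highest fasted over fed ratios were those of Cyp4a32 (log2 5.05, 33.1-fold), Cyp4a14 (4.55), Cyp4a10 (4.50) and Cyp4a31 (4.25), whose close paralogs can share probes, followed by the acyl-CoA thioesterase gene Acot1 (3.90), Mfsd2a (3.60), Asic5 (3.59), Acot3 (3.40), Vnn1 (3.23) and Acot5 (3.10). Thrsp, a lipogenic gene, was 39.5-fold lower (-5.30) and fatty acid synthase, Fasn, 11.6-fold lower (-3.54). Gsta1 (-3.72), Cyp2c70 (-3.58), Srebf1 (-3.43), Tgtp2 (-3.38), Angptl8 (-3.33), Hsd3b5 (-3.30) and Mid1ip1 (-3.26) were also among the 10 lowest. Of 45 fatty acid oxidation genes 28 were at least 2-fold higher and none lower (median 1.12), and of 31 genes of fatty acid synthesis and glycolysis 19 were lower and none higher (median -1.42). Cholesterol synthesis genes had a median of -0.97, 12 of 26 being lower, with Insig1 at -2.54 and Fdps at -2.44. Of 29 lipid droplet genes 12 were higher, with Plin4 at 2.67, Cidec at 2.48 and G0s2 at 2.28. Fgf21 was at 2.06, Pck1 at 2.01 and Apoa4 at 1.69, and 6 of 18 CREBH targets were 2-fold higher (median 0.45). Interferon genes were lower after fasting, 13 of 36 by 2-fold (median -0.70). Proliferation genes had a median of -0.42 over 20 genes, and Rrm2 (-1.55) alone was lower by 2-fold. In total 490 of 11439 genes were 2-fold apart, 270 higher and 220 lower. This comparison crosses arrays, and without normalization between them 1080 genes were higher and 71 lower, the cholesterol synthesis median being -0.39 and the interferon median -0.19.

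In KO liver the fasting difference of fatty acid oxidation and lipogenic genes was of the same direction, while those of cholesterol synthesis genes, interferon genes and CREBH targets differed from WT. Cyp4a14 was 824-fold higher in the fasted than in the fed KO pool (log2 9.69), Cyp4a10 116-fold (6.85), Cyp4a31 109-fold (6.77), Cyp4a32 78.4-fold (6.29) and Vnn1 47.7-fold (5.58), followed by Ehhadh, a peroxisomal oxidation gene (3.97), Retsat (3.90), Asic5 (3.71), Acot1 (3.70) and Acot5 (3.53). The fold of Vnn1 is uncertain, since its fed KO signal (log2 6.18) was among the dimmest measured. Thrsp was at -4.80, Apoa4 at -4.30, Gsta1 at -3.68, Slc22a7 at -3.30, Angptl8 at -3.23, Elovl6 at -3.08, Hsd3b5 at -3.07, Srebf1 at -3.06, Cyp2c70 at -2.94 and Scd1 at -2.88. Of 45 fatty acid oxidation genes 32 were higher (median 1.31), and 19 of 31 lipogenic and glycolytic genes were lower (median -1.29). Cholesterol synthesis genes had a median of 0.27, with 6 of 26 higher, among them Sqle (1.68) and Fdft1 (1.39), and Insig1 lower (-1.49). Interferon genes had a median of 0.06, with H2-Aa of MHC class II higher (1.24) and Bst2 lower (-1.86). Kupffer cell and macrophage markers had a median of 0.42, above all random lists, with 17 of 20 above 0 and none 2-fold higher, against a median of 0.10 in WT. CREBH targets had a median of 0.16, with 10 of 18 above 0, inside the range of random lists. None was 2-fold higher and 3 were lower, Apoa4, Elovl2 (-1.84) and G6pc (-1.04). Fabp2 was at -2.07 against 1.26 in WT. Proliferation genes had a median of -0.50, 6 of 21 being lower by 2-fold. In total 552 of 11784 genes were 2-fold apart, 305 higher and 247 lower. Without normalization between arrays the counts were 1163 and 80, and scanner-processed signals gave 1073 genes.

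**Figure D3:**
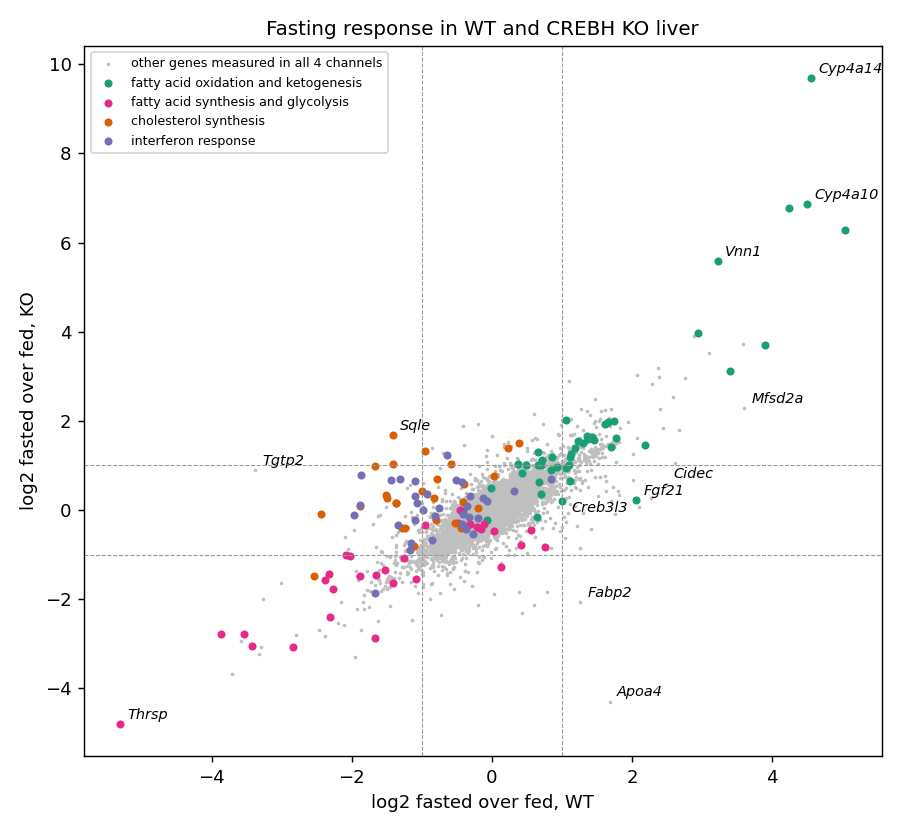
Log2 fasted over fed signal per gene in the WT pools on the x axis and in the KO pools on the y axis, for genes measured in all 4 channels, with dashed lines at 2-fold. Cyp4a14 is at 4.55 in WT and 9.69 in KO, Thrsp at -5.30 and -4.80, and Apoa4 at 1.69 and -4.30.

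Across 11287 genes measured in all 4 channels, the fasting differences of WT and KO had a Pearson r of 0.80 and a Spearman rho of 0.76, and genes are not independent replicates. Of the genes higher by 2-fold, 192 were shared by 267 in WT and 305 in KO, where independent lists would share 7.22. Of the lower genes 131 were shared by 218 and 247, against 4.77. Both fasting comparisons used the same pair of arrays. The covariance between genes was 0.185, and that of the noise between spots of one probe was 0.0014.

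The KO over WT ratio differed most between feeding states for Apoa4, Cyp4a14 and Tgtp2. Fasted minus fed log2 ratios were 5.13 for Cyp4a14, 4.27 for Tgtp2, 3.09 for Sqle, 2.66 for Hmgcs1 and 2.65 for Igtp, then Cyp4a31 (2.52), Idi1 (2.45), Fdps (2.36), Cyp4a10 (2.35) and Vnn1 (2.35). At the other end were Apoa4 (-5.99), Fabp2 (-3.32), Gpc1 (-2.75), the cornified envelope gene Sprr1a (-2.74), Tnfaip8l1 (-2.64), Elovl2 (-2.23), Lpin1 (-2.02), G0s2 (-2.01), Moxd1 (-1.95) and the water channel gene Aqp4 (-1.91). All 26 cholesterol synthesis genes had differences above 0, 16 of them at least 2-fold (median 1.14). Among 34 interferon genes 30 lay above 0, 13 exceeded 2-fold and none was 2-fold lower (median 0.65), with H2-Ab1 at 2.10 and H2-Eb1 at 1.98. CREBH targets had a median of -0.77, with 6 of 18 lower, and the clock list one of -0.38, with Dbp (-1.39), Usp2 (-1.36) and Per1 (-1.19) lower. Kupffer cell and macrophage markers had a median of 0.25, Marco being at 1.19. A gene-specific dye effect cancels in this difference, since both arrays had the same dye orientation. It counted 155 of 11287 genes, 87 higher and 68 lower, and 340 with scanner-processed signals. Centring on the median of all spots gave 66 higher and 124 lower.

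Asns, Cxcl14 and Moxd1 were at least 2-fold higher in KO on both arrays, and Mfsd2a, Mt2 and Gadd45g at least 2-fold lower. For the genes not given above in both states, the log2 ratios were 1.05 for Cxcl14 when fasted, -1.67 for Mt2 when fasted, and -1.78 fed and -1.29 fasted for Gadd45g. Independent lists would share 0.07 higher and 0.21 lower genes. In opposite directions 3 genes were 2-fold apart on both arrays, where independent lists would share 0.256. Sharing above the number for independent lists was thus not confined to genes of the same direction. Because KO was labelled with Cy5 both times, a dye effect of a gene would also repeat. Across 11287 genes the ratios of both arrays had a Pearson r of 0.26 and a Spearman rho of 0.30, and with median centring the r was 0.58.

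Few genes near Creb3l3 were 2-fold apart between KO and WT. Within 10 Mb, by the neighbourhood in the GRCm38.p6 gene table, 0 of 197 measured genes were 2-fold apart in the fed state (exact 95% interval up to 1.86%), against 0.564% elsewhere. In the fasted state 3 of 212 were, or 1.42% (0.293% to 4.08%), against 0.772%, a value inside the interval. The intervals cover only the number of genes counted.

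By the yardstick of matched random lists, 16 of 28 list medians lay outside the central 95% in the fed and 11 of 28 in the fasted comparison. When fed, these were all lists of the fed paragraph above, cholesterol synthesis with 24 of 26 genes below 0, the urea cycle, fatty acid synthesis and bile acid lists, and endothelial, red cell, proliferation and fat tissue genes. When fasted, they were the lists of the fasted paragraph except the apolipoprotein and lipid droplet lists, the urea cycle list, and the Kupffer cell, stellate cell and fat tissue markers. Hepatocyte markers had medians of 0.05 fed and 0.05 fasted, endothelial markers -0.08 and 0.03, stellate cell and fibroblast markers 0.07 and 0.11, bile duct markers -0.05 and 0.08, and pancreas and gut markers 0.04 and 0.01. Fasted medians were 0.12 for Kupffer cell and macrophage markers, 0.10 for lymphocyte markers, -0.01 for neutrophil markers and -0.07 for the clock list. Red cell markers were at 0.18 and -0.07, proliferation genes at 0.15 and 0.02, and the 3 measured fat tissue markers at 0.48 and 0.80, with Fabp4 past 2-fold when fasted and at -0.31 when fed. Genes of xenobiotic metabolism had medians of -0.07 and -0.04, the acute phase list -0.09 and -0.01, bile acid genes -0.09 and -0.07, the growth hormone and hepatokine list 0.07 and -0.08, female-predominant genes 0.03 and -0.08, and male-predominant genes 0.06 and -0.01. In fed liver the apolipoprotein list was at -0.06, gluconeogenesis at 0.01, lipid droplet genes at 0.02, cholesterol synthesis at -0.21, fatty acid synthesis at -0.13, fatty acid oxidation at -0.13 and the urea cycle list at -0.18, the last being -0.16 when fasted. The fed medians of fatty acid oxidation, fatty acid synthesis, the urea cycle list and bile acid genes, and the fasted median of the urea cycle list, were above 0 with arrays centred on the measured genes. With arrays centred on all spots these were above 0 too, as were the fed medians of cholesterol synthesis (0.69) and endothelial markers (0.68).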

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

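The tests of dye, cell makeup, fasting strength and sampling time in this part were all chosen after the results they bear on had been seen. Apoa4, Cyp4a14 and Sprr1a were 2-fold apart between KO and WT in opposite directions in fed and fasted liver, and the difference was not tested, since each state had 1 array. For Apoa4 the fasted minus fed log2 ratio was -5.99 (1.68 fed, -4.31 fasted), for Cyp4a14 it was 5.13 (-3.77 and 1.36) and for Sprr1a -2.74 (1.15 and -1.59).

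Interferon-inducible and antigen-presentation genes were lower in the fed KO pool (median -0.75 over 34 genes, ranging from -1.22 to -0.18 over the alternatives). A dye effect per gene would repeat on both arrays, but the fasted minus fed ratios had a median of 0.65, 30 of 34 lying above 0, which argues against dye as the whole cause. Fewer macrophages and lymphocytes in the KO pool would lower all their markers by about as much, and 31 such markers, none of them in the interferon list, had a median of -0.19 (scaled median absolute deviation 0.22), 1 of them as low as the list, although Marco (-0.91) and Cd5l (-0.57) were lower. The list was lower in fasted than in fed WT liver (-0.70) and not in KO (0.06), a gap of -0.76. This gap rests on the same channels as the fasted minus fed ratios. By these medians the fed WT pool stood apart from the 3 others, but they cross arrays. Without normalization between arrays the median of all genes shifted up by 0.45 in WT and 0.43 in KO. Which pool stood apart therefore depends on that normalization. Kupffer cell and macrophage markers differed in the same direction by less (0.10 in WT, 0.42 in KO), so a part played by these cells stays open. A state of some mice in the fed WT pool, such as an infection, and an effect of the genotype in fed liver cannot be told apart, because each group is 1 pool.

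Cholesterol synthesis genes were higher in the fasted KO pool (median 1.04 over 26 genes, ranging from 0.89 to 1.75). The fasted minus fed ratios, in which a dye effect per gene cancels, had a median of 1.14 with all 26 genes above 0, which argues against dye as the whole cause. A weaker fast in the KO pool would leave fasting-induced genes lower there. Fatty acid oxidation genes had a median KO over WT ratio of 0.076 (47 genes), which argues against it as the whole cause in these pools. The standard error of 0.064 is over genes taken as independent, and it holds no difference between mice or pools. Gluconeogenesis genes (-0.27, but 0.014 with arrays centred on the measured genes) and genes of fatty acid synthesis and glycolysis (0.18) lay on the side a weaker fast would give. In the latter list the 3 members past 2-fold, Fads2 (-1.94), Scd1 (-1.92) and Elovl5 (-1.86), were lower, against its median. A part played by a weaker fast stays open. An effect of the genotype in fasted liver stays open as a hypothesis, as do other differences between the pools, which were not tested.

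The clock list had a median fed KO over WT ratio of 0.35 over 16 genes, none of them 2-fold apart. Genes with the phase of Dbp had a mean log2 KO over WT ratio of 0.54 (8 genes) and genes with the phase of Arntl one of -0.17 (3 genes), a difference of 0.70 that goes with another time of day of sampling. It leans on Arntl alone among the 3 (-0.50, against -0.08 for Clock and 0.08 for Nfil3), and several Dbp-phase values were known when the bound was set, so the test is weak. Fasted over fed ratios in WT and KO were 1.31 and -0.06 for Usp2, and 1.51 and 0.32 for Per1. Those of Dbp were 1.0 and -0.39, of Tef 1.1 and 0.28, and of Nr1d2 0.45 and -0.01. With the fed KO over WT ratios, these genes were lowest in the fed WT pool. So was Nr1d1 (0.08, -0.49), by little, which was also highest in the fed KO pool. Hlf (-0.14, -0.50) was highest in the fed KO pool and not lowest in the fed WT pool. Per2 (0.04, -0.01) hardly differed between the pools. Whether the fed WT pool also stood apart for the interferon list depended on the normalization between arrays. Sampling times are not given in the sources used here, the phase difference in fasted liver was -0.11, and a state of the fed WT pool and a genotype effect on clock output stay open, untested.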

How the results depend on the processing

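Every alternative below was planned before the data were examined, except centring on the median of the measured genes. KO and WT share each array, and a paired test of the mean ratio over both arrays, with 1 residual degree of freedom, was not run. For KO over WT fed (63, 18 higher, 45 lower) an offset of 10 gave 97 with 31 higher, and scanner-processed signals and the authors' value table both gave 173, 62 and 111. For KO over WT fasted (97, 44, 53) they gave 193, 88 and 105, and 195, 90 and 105. For the difference of ratios (155, 87, 68) they gave 340, 203 and 137, and 342, 205 and 137. For fasting, processed signals gave 882, 426 and 456 in WT and 1073, 579 and 494 in KO. No normalization between arrays gave 1151, 1080 and 71 in WT and 1243, 1163 and 80 in KO, with the median of all genes shifted by 0.45 and 0.43.

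Centring on the median of all spots in place of loess shifted the median of measured genes by 0.76 fed, 0.56 fasted and -0.16 in the difference. Counts became 3112, 3103 and 9 fed, 956, 940 and 16 fasted, and 124 lower in the difference, Creb3l3 went to 0.31 and -1.11, and the r between arrays from 0.26 to 0.58. Fed list medians turned to 0.72 (CREBH targets), 0.87 (fatty acid oxidation), 1.02 (urea cycle), 0.94 (fatty acid synthesis), 0.69 (cholesterol synthesis), 0.99 (bile acids), 0.57 (Kupffer cells), 0.68 (endothelium), 0.14 (lymphocytes) and 0.49 (neutrophils), fasted ones to 0.58 (gluconeogenesis), 0.73 (urea cycle) and 0.44 (interferon), and those of the difference to -0.20 (fatty acid synthesis), -0.13 (acute phase) and -0.17 (endoplasmic reticulum stress).

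Centring on the measured genes gave 127 genes fed, 76 higher, and 73 higher fasted, with Creb3l3 at -0.46 and -1.68. It turned fed medians to 0.10 (fatty acid oxidation), 0.24 (urea cycle), 0.17 (fatty acid synthesis) and 0.21 (bile acids), fasted ones to 0.014 (gluconeogenesis) and 0.16 (urea cycle), and those of the difference to -0.033 (fatty acid synthesis) and 0.084 (female-predominant genes). Male-predominant genes in fasted over fed KO were at 0.17 without normalization between arrays, and fat tissue markers in the difference at -0.005 with dim probes kept. The cause was not tested beyond the shifts given. No named gene at least 2-fold apart changed direction under any alternative run for it. The fasted cholesterol synthesis median ranged from 0.89 to 1.75, the fed interferon median from -1.22 to -0.18 and the fasted median of CREBH targets from -0.88 to -0.01. Low signal over background limits the ratios of dim genes.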

Other observations

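Endothelial markers had median fasted over fed ratios of 0.26 in WT and 0.47 in KO over 20 genes, of which 1 was 2-fold higher in each genotype, the sinusoidal marker Lyve1 at 1.35 and 1.51. In the stellate cell and fibroblast list the medians were -0.08 and 0.07 over 19 genes, and 3 genes were 2-fold lower in each genotype, among them Col3a1 (-1.67 and -1.68) and Col1a1 (-1.30 and -1.42). The bile duct keratin gene Krt23 was higher after fasting (2.28 and 2.83), although the medians of the bile duct list were 0.02 and 0.06. Male-predominant genes had medians of -0.11 in WT and -0.26 in KO, with Hsd3b5 among the lowest in both, and the KO median was 0.17 without normalization between arrays. Among unnamed probes, 15 of 6674 measured in the fed and 31 of 8096 in the fasted KO over WT comparison were at least 2-fold apart.

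One test was set before its result was seen: passenger DNA around the targeted locus could make neighbours differ in both feeding states. Of 196 genes within 10 Mb of Creb3l3, 1 was at least 1.5-fold apart in the same direction on both arrays (0.510%, against 0.496% elsewhere), which lay at the 56.5th percentile of 10000 matched random sets and below the upper bound of 1.53% set for them. The gene was Derl3, an endoplasmic reticulum degradation gene (0.86 fed, 1.21 fasted). The share argues against many passenger genes. A few are not excluded, since only a share above 1.53% would have counted as such an effect.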
